A study of Mus musculus with 18 samples.

How the data were processed

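Colon RNA of ICR mice, an outbred laboratory strain, was sequenced in 18 libraries. The labels give 3 treatments, each for 44 days: saline, a compound Suanzaoren (jujube kernel) capsule by gavage, and Jinhua Hecha, a fermented green tea, by gavage. The titles also carry a letter, C or X, whose meaning the labels do not state. The libraries were therefore handled as 2 sets, C and X, with 3 libraries of each treatment in each set. The design text speaks of 3 mice per treatment while 6 libraries per treatment were available, and nothing in the labels ties libraries to mice. The p-values below therefore measure the spread between these libraries, which may in part be technical.

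Per the labels' protocols, libraries were made from 5 µg of total RNA with oligo(dT) beads. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR (no version) were used, in roles that are not given. Per the file headers, the authors deposited a single table with a read count and an FPKM value for every gene and library. The counts were whole numbers, not normalized, and the deposited FPKM values were the same counts divided by gene length and library total. The labels list a human build, but the identifiers and coordinates in the table matched the mouse GENCODE annotation of GRCm38, which was used for all positions here. Whether counting used strand is not given in the sources used here, so reads of a gene and its antisense partner cannot be told apart. How reads that map to near-identical copies were counted is not given in the sources used here. The nuclear copy Gm28437 had 0.993 to 1.006 times the count of the mitochondrial gene mt-Co3 in every library, so the 2 were not told apart. Values of Hspa1a and Hspa1b, of haemoglobin genes, of immunoglobulin segments and of ribosomal protein genes are therefore uncertain at the level of the single gene.

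The plan fixed before the data were examined assumed FPKM alone and named edgeR for the case that counts were present. Counts were present, so edgeR 4.0.16 (R 4.3.3) was used: TMM scaling, a filter on low counts (filterByExpr, minimum count 10) and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Each set was fitted alone with its 9 libraries for 3 pairwise comparisons. All 18 libraries were fitted together for the tea and capsule effects averaged over both sets, for the difference of each effect between the sets, and for set X against set C. The filter left 20964 genes in set C, 20889 in set X and 22380 in the joint fit. Residual degrees of freedom were 6, 6 and 12 and biological coefficients of variation 0.556, 0.559 and 0.59. Log2 fold changes are given ± a standard error, and levels as TMM-scaled CPM (counts per 1e6 counts of the library) ± SD of the 3 libraries of a group. This standard error was derived from the test itself, as the absolute log2 fold change over the square root of the quasi-likelihood F. It therefore holds nothing beyond the fold and the outcome of its test.

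Depth ran from 59206980 to 76830278 counts per library, and the differences between libraries far exceeded counting noise. Chi-square per degree of freedom was 66.5 to 1418.7 over the 18 pairs of libraries of the same group, so none was a second copy of another. A group with no count in any library was given a floor of 3 counts per library, and a fold against it is a lower bound that covers counting error only.

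Gene lists for pathways and cell types, 69 in all, were written before the data were examined. They were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, for lists with at least 5 tested members, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. A list that stood higher or lower did so against the other genes tested. The list of glutamatergic synapse genes follows the series title, so the study chose its theme. The KEGG terms in the deposited annotation were tested in the same way. In addition, 3 lists of lung, cartilage and bone, and epidermis genes were written after those transcripts had been seen.

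Genes were named by a rule fixed before the data were examined. Among genes past the threshold with a symbol other than a clone name, the 10 largest rises and 10 largest falls were taken. Where fewer than 5 passed, the 5 with the smallest p in each direction were added as not past it. For each list described, the 2 members with the smallest p were taken, together with Xist, Y-linked genes and leading cell type markers as levels. Hp, Ager, Lipe, Ntrk2, Actn3, H19, Sbsn and Col11a2 in the capsule comparison of set C, Zeb2 in the averaged tea effect, the tissue markers Lep, Adipoq and Col2a1, and the genes of the closing observations were chosen after their values were seen.

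On simulated counts drawn from the real means and library sizes, the tea comparison of set C (20964 genes) recovered 0 of 100 genes changed 2-fold and 11 of 100 changed 4-fold, with 1 unchanged gene called. The averaged tea effect (22380 genes) recovered 36 of 100 and 75 of 100, with 5 unchanged genes called. With the GC trend removed these numbers were 0, 10, 35 and 75. A simulated list of 40 genes shifted by 1 on the log2 scale had a camera adjusted p of 7.86e-28 in set C and 1.46e-44 in the joint fit, and 0 of 68 other lists were called. Simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera calls unshifted lists in real libraries, where genes move together.

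Alternatives fixed before the data were examined were limma on log2(FPKM + 1) for genes with FPKM of at least 1 in 3 libraries, a pseudocount of 0.1, limma without a variance trend, library weights, scaling to library totals or by median ratios, no filter, a mean FPKM of at least 5, other libraries in the fit, DESeq2 1.42.0, and leaving out each library. Alternatives chosen after seeing the data were a term for library kind, the first principal component as a covariate, leaving out 6 libraries that stood apart on it, leaving out mitochondrial genes, and the removal of each library's trend with transcript GC content or length. Library kind was defined from the data, by at least 10 CPM of the cartilage gene Col2a1 and the lung gene Sftpc. Tables were handled with data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 (Python 3.11.15), and plots were drawn with matplotlib 3.10.9. Results of some single genes are not reported here.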

Results

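Gene expression was measured in the colon of ICR mice after 44 days of saline, of a compound Suanzaoren capsule (a jujube kernel preparation) or of Jinhua Hecha, a fermented green tea. The series title names sleep, glutamatergic synapses and the gut microbiota as its subject. The 18 libraries formed 6 groups of 3: saline, capsule and tea, each in set C and in set X. Libraries are named by the codes in their titles: NC for saline, FFZR for capsule and JHHCG for tea, then the letter of the set and a number. Depth was 59206980 to 76830278 counts per library, and mitochondrial transcripts took 5.48 to 24.88% of counts. Errors of log2 fold changes are standard errors, errors of levels are SD, and n is 3 libraries per group throughout.

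Transcripts typical of other tissues were abundant in some colon libraries. Col2a1, the main collagen of cartilage, stood at 68.4 to 89.6 CPM in 5 libraries and at 0 to 0.28 CPM in the other 13. The same 5 libraries held 51.5 to 72.8 CPM of Lep, the fat cell hormone leptin, against 0 to 0.502 CPM elsewhere, and 55.5 to 69.6 CPM of Hp, the plasma protein haptoglobin, against 0.35 to 5.44 CPM. They were the 3 saline libraries of set C, NCX_124 and FFZRX_139. The fat marker Adipoq was less sharply divided, at 54.6 to 81.5 CPM in them and 0 to 30.8 CPM in the other 13. Sftpc, a surfactant protein of lung alveoli, stood at 59.6 to 94.4 CPM in these 5. It was also present in 6 libraries without Col2a1: all 3 tea libraries of set C, FFZRX_238, FFZRX_268 and JHHCGX_129. The remaining 7 libraries, among them all 3 capsule libraries of set C, had neither transcript at 10 CPM. In set C these kinds of library coincided with treatment, and kind and treatment cannot be told apart there, whereas each treatment of set X held more than 1 kind.

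**Figure D1:**
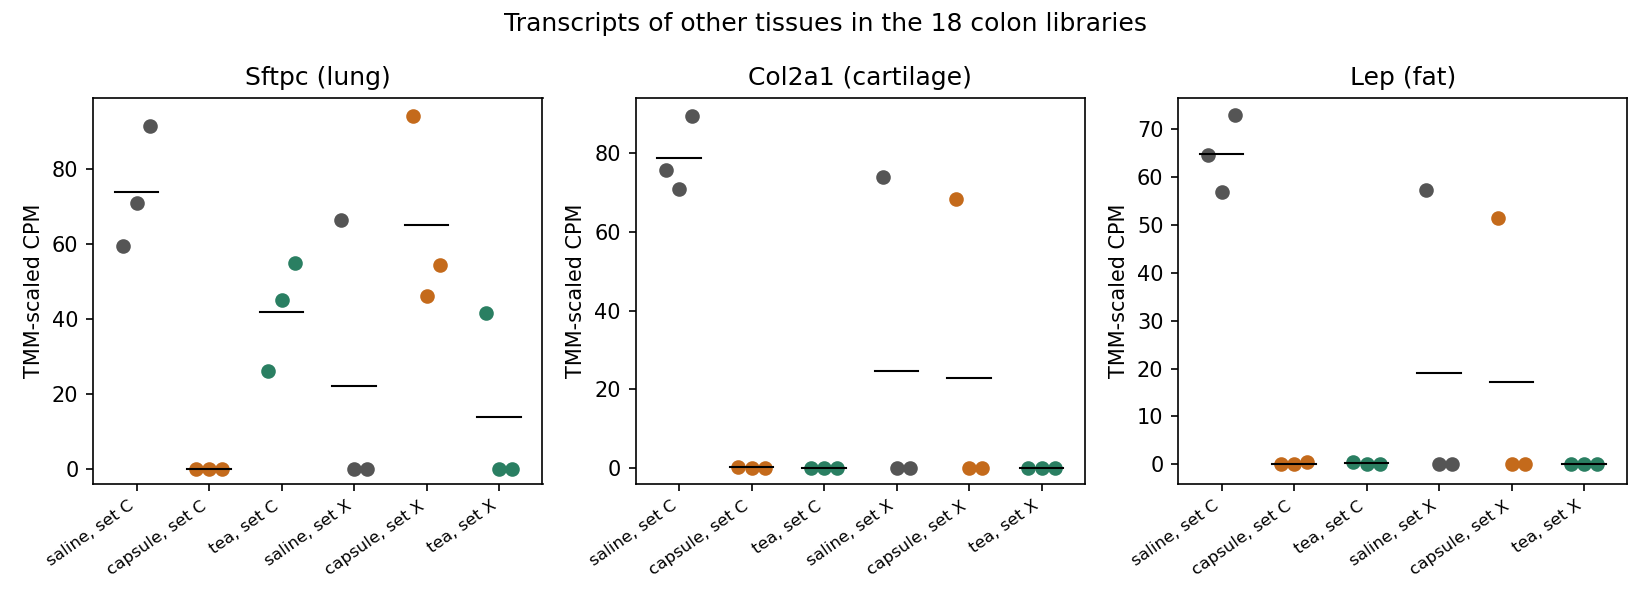
TMM-scaled CPM (linear axis) of Sftpc, Col2a1 and Lep in each library of the 6 groups; dots are libraries and lines are group means. Col2a1 and Lep stood above 50 CPM in 5 libraries, 68.4 to 89.6 and 51.5 to 72.8 CPM, and at or below 0.502 CPM in the other 13.

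Libraries also differed in their levels of mucin, muscle and mitochondrial transcripts. The first principal component took 26.7% of the variance and set 6 libraries apart: NCC_17, FFZRC_24, JHHCGC_48, NCX_134, NCX_147 and JHHCGX_256. In them Muc2, the goblet cell mucin, stood at 30.4 to 346.2 CPM against 386.1 to 2945.1 CPM in the other 12. Myh11, the smooth muscle myosin, stood at 1978.8 to 7606.6 CPM against 399.5 to 1986.6 CPM. Epcam, an epithelial adhesion molecule, was not lower in them (1170.6 to 2738.6 against 1359.4 to 2188.4 CPM). Mitochondrial transcripts took 12.22 to 24.88% of their counts against 5.48 to 11.07%. Each group of set C held 1 such library, while set X held 2 in saline, 1 in tea and none in capsule.

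The tea comparison of set C asked how colon expression differed between mice given tea and mice given saline. Genes of skeletal muscle and of fat cells stood lower than other genes. All 12 skeletal muscle genes had negative folds with a median of -3.37 (camera adjusted p = 1.69e-17; adjusted p = 0.303 with an estimated correlation). Adjusted over the list alone, 5 were lower; the fast-fibre actinin Actn3 was at -3.78 ± 0.57 and the myosin light chain Mylpf at -3.32 ± 0.68. Of 12 adipocyte genes 11 were negative, median -1.97 (adjusted p = 2.56e-08; adjusted p = 0.435 with an estimated correlation). Of these, 3 were lower adjusted over the list alone; the lipase Lipe stood at -1.67 ± 0.26 and Lep at -8.33 ± 1.70. All 3 saline libraries of this set held 51.5 CPM of Lep or more, and the tea libraries held at most 0.502 CPM. Interferon response genes stood higher, with 35 of 38 positive and a median of 1.35 (adjusted p = 8.36e-06; adjusted p = 0.887 with an estimated correlation; 0 adjusted over the list alone). Examples were the GTPase Gbp4 at 1.15 ± 0.52 and the peptide transporter Tap1 at 1.56 ± 0.71. T cell genes had a median of 1.33 (adjusted p = 0.00715; adjusted p = 0.887 with an estimated correlation; 0 adjusted over the list alone) and B cell genes one of 0.9 (adjusted p = 0.763).

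Genes of the circadian clock stood lower in tea than in saline of set C, with 17 of 24 negative and a median of -0.55 (adjusted p = 0.0117; adjusted p = 0.706 with an estimated correlation). Adjusted over the list alone 1 was lower, the clock output factor Dbp at -3.30 ± 0.74, and the clock repressor Per3 stood at -1.29 ± 0.36. The KEGG term for circadian rhythm, with 30 genes, missed the threshold for tea in set C, set X and the averaged effect (medians -0.043, -0.28 and -0.223; adjusted p of 0.323 to 0.441). Of 53 glutamatergic synapse genes 43 were negative, median -0.25 (adjusted p = 0.00402; adjusted p = 0.706 with an estimated correlation; 0 adjusted over the list alone). The study chose this theme, so the list is not independent evidence of its direction. Among its members the kainate receptor subunit Grik4 stood at -0.95 ± 0.43. General neuron, enteric neuron, synaptic vesicle and glia genes had medians of -0.23, -0.23, -0.28 and -0.45 (adjusted p of 0.071 to 0.421). Nuclear genes of oxidative phosphorylation stood slightly higher, with 50 of 57 positive and a median of 0.16 (adjusted p = 0.000456; adjusted p = 0.887 with an estimated correlation; 0 adjusted over the list alone), such as Ndufs7 at 0.34 ± 0.17 and Cox5a at 0.37 ± 0.22.

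No single gene passed the threshold in this comparison with edgeR (0 of 20964), and 668 had an unadjusted p under 0.05. Limma on FPKM called 50 and DESeq2 159. The lowest p belonged to Col11a2, a cartilage collagen (-3.00 ± 0.30), and Hp (-4.04 ± 0.42), both at an adjusted p of 0.0623. Npr3, the natriuretic peptide clearance receptor, stood at -5.27 ± 0.63 (adjusted p = 0.0867). Oc90 and Matn1 were at 9.39 ± 1.43 and 6.44 ± 0.38 CPM in saline and at 0 in all 3 tea libraries. On the positive side stood Sprr2b at 4.09 ± 0.84, Gpank1 at 0.87 ± 0.22, Tgm4 at 3.05 ± 0.80, Rfx1 at 0.64 ± 0.17 and Tnfsf9 at 1.70 ± 0.47, with adjusted p of 0.455 to 0.805. Leaving out single libraries gave 0 to 11 genes; it was 11 without FFZRC_24, 4 without FFZRC_5, 2 without FFZRC_12 and 1 without JHHCGC_7 or JHHCGC_48.

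The capsule comparison of set C gave 23 genes below saline and none above. Of these, 5 were members of the lung list, 4 of the cartilage and bone list and 1 each of the adipocyte, skeletal muscle and epidermis lists. Scgb1a1, the club cell secretoglobin of airways (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958), stood at 97.9 ± 7.35 CPM in saline and 0 in capsule, at least 2172-fold lower (adjusted p = 0.0138). Sftpc (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081) fell from 74.0 ± 16.2 CPM to 0, at least 1641-fold lower (adjusted p = 0.00284). The cartilage genes Col9a1, Acan and Matn1 were at least 405-fold, 176-fold and 143-fold lower, and Oc90, of the inner ear, at least 208-fold lower. Cxcl15, Sftpd, Crispld1 and Cyp2b10 were at least 109-fold, 85-fold, 33-fold and 27-fold lower. Hp (chromosome 8, 109575128 to 109579172) fell from 65.0 ± 5.32 to 0.702 ± 0.356 CPM, a log2 fold change of -6.50 ± 0.47 (adjusted p = 0.00348). H19, an imprinted noncoding RNA (chromosome 7, 142575529 to 142578143), stood at -6.55 ± 0.89 (adjusted p = 0.047), Lipe at -2.39 ± 0.27 (adjusted p = 0.0214) and Actn3 at -4.60 ± 0.59 (adjusted p = 0.0352). Ager, a receptor abundant in lung, fell by 2.67 ± 0.27 on the log2 scale, Ntrk2 by 4.20 ± 0.42, the skin gene Sbsn by 3.22 ± 0.32 and Col11a2 by 2.95 ± 0.30. All 3 saline libraries held Col2a1, Lep and Sftpc above 50 CPM, while the capsule libraries held no Sftpc and at most 0.285 and 0.498 CPM of Col2a1 and Lep.

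Gene groups were tested in the same comparison. Skeletal muscle genes had a median of -4.64 with 12 of 12 negative (camera adjusted p = 2.41e-17; adjusted p = 0.206 with an estimated correlation; 10 lower adjusted over the list alone), among them Tnnt3 at -6.60 ± 1.10. Adipocyte genes had a median of -4.09 with 11 of 12 negative (adjusted p = 1.43e-13; adjusted p = 0.31 with an estimated correlation; 10 lower adjusted over the list alone), among them Lep at -8.73 ± 1.75. In set X the capsule comparison did not repeat these falls, with medians of 2.23 for skeletal muscle genes and 0.04 for adipocyte genes. Red blood cell genes stood lower, 5 of 6 with a median of -1.35 (adjusted p = 3.55e-07; adjusted p = 0.206 with an estimated correlation; 4 lower adjusted over the list alone), with Hbb-bs at -1.41 ± 0.21 and Hba-a2 at -4.13 ± 0.62. All 15 general neuron genes were negative, median -0.61 (adjusted p = 4.6e-06; adjusted p = 0.663 with an estimated correlation; 1 lower adjusted over the list alone), with the neuronal splicing factor Rbfox3 at -1.96 ± 0.40 and Map2 at -1.31 ± 0.46. Of 53 glutamatergic synapse genes 41 were negative, median -0.24 (adjusted p = 0.00316; adjusted p = 0.663 with an estimated correlation; 0 adjusted over the list alone), again a theme chosen by the study. The postsynaptic scaffold Shank3 stood at -1.06 ± 0.33.

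Interferon response genes stood higher in capsule than in saline of set C, 37 of 38 with a median of 1.42 (adjusted p = 4.43e-06; adjusted p = 0.812 with an estimated correlation), with the GTPases Iigp1 at 2.80 ± 0.98 and Gbp4 at 1.46 ± 0.52. All 11 genes of MHC class II presentation were positive, median 0.96 (adjusted p = 0.00224; adjusted p = 0.729 with an estimated correlation), with their transactivator Ciita at 2.04 ± 0.56 and H2-DMa at 1.0 ± 0.56. Lists of immune cell markers had medians of 1.33 for T cells, 1.24 for B cells and 1.02 for plasma cells and missed the threshold (adjusted p of 0.0553, 0.167 and 0.14). Between the single capsule and saline library of set X with cartilage transcripts, MHC class II genes went the other way, 1 of 11 positive with a median of -1.06, and so did B cell genes, 0 of 11 with a median of -3.24. Cytosolic ribosomal protein genes stood lower, 69 of 74 with a median of -0.52 (adjusted p = 6.62e-06; adjusted p = 0.812 with an estimated correlation), with Rps29 at -1.54 ± 0.38 and Rps28 at -1.73 ± 0.45. In the interferon, MHC class II and ribosomal lists 0 genes passed adjusted over the list alone. The count of 23 genes fell to 0 with a term for library kind, fitted over all 18 libraries. There Scgb1a1, Sftpd, Cyp2b10 and Ager reversed to 0.78, 0.13, 0.81 and 0.18, while the other named genes of the 23 did not reverse. In set C kind coincided with treatment, so the term rested on libraries of set X. The count fell to 2 without any 1 of the 3 saline libraries and to 6 and 3 without FFZRC_5 and FFZRC_12. It rose to 240 without FFZRC_24.

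Tea and capsule were compared directly in set C. The 3 genes that differed were lung genes absent from capsule: Sftpc at 42.0 ± 14.6 CPM in tea, at least 931-fold higher (adjusted p = 0.00388), Scgb1a1 at 90.2 ± 74.4 CPM, at least 2000-fold higher, and the lung chemokine Cxcl15 at 2.66 ± 1.03 CPM, at least 59-fold higher (both adjusted p = 0.0353). The 3 tea libraries were of the kind with lung transcripts. Clock genes stood lower in tea than in capsule, 18 of 24 with a median of -0.36 (adjusted p = 0.000169; adjusted p = 0.654 with an estimated correlation), and 6 were lower adjusted over the list alone, with the repressor Nr1d1 at -1.21 ± 0.26 and Dbp at -3.16 ± 0.74. Oxidative phosphorylation genes stood higher, 42 of 57 with a median of 0.41 (adjusted p = 2.21e-08; adjusted p = 0.901 with an estimated correlation; 5 higher adjusted over the list alone), with Atp5k at 1.23 ± 0.25 and Ndufa3 at 1.12 ± 0.23, while the 13 mitochondrially encoded genes were all negative with a median of -0.9 (adjusted p = 0.172). The fold changes of this comparison had a Spearman correlation of 0.25 with GC content and -0.21 with transcript length across genes; with each library's GC trend removed the oxidative phosphorylation list had an adjusted p of 2.15e-07. Ribosomal protein genes stood higher, 67 of 74 with a median of 0.47 (adjusted p = 1.85e-05), with Rps29 at 1.46 ± 0.38, and all 11 MHC class II genes stood lower with a median of -0.91 (adjusted p = 0.00023), with H2-Ab1 at -1.23 ± 0.59 and H2-DMb1 at -1.05 ± 0.57. Both had an adjusted p of 0.901 with an estimated correlation and 0 genes adjusted over the list alone. Glutamatergic synapse genes had a median of -0.05 (adjusted p = 0.753).

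Among genes not past the threshold in this comparison, Ager stood at 2.11 ± 0.27 (adjusted p = 0.121). Sftpd, Crispld1, Cyp2b10 and Scgb3a2 were at 1.78, 0.5, 0.782 and 1.52 CPM in tea and 0 in capsule. Gprin3 stood at -1.003 ± 0.18, Cyp2d9 at -0.92 ± 0.17 and Lnx1 at -0.97 ± 0.19 (adjusted p of 0.599 to 0.625), and Wnt16 and Wdr93 were at 0.463 and 0.209 CPM in capsule and 0 in tea. The count of 3 became 1 without any 1 saline library, FFZRC_5, JHHCGC_7 or JHHCGC_19, and 9 without FFZRC_24.

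In set X, tea libraries stood above saline libraries in genes of cholesterol synthesis, oxidative phosphorylation, ribosomes and the epithelial barrier, and below them in heat shock and fibroblast genes. All 22 cholesterol genes were positive, median 0.77 (adjusted p = 1.47e-10; adjusted p = 0.65 with an estimated correlation), and 16 were higher adjusted over the list alone, such as the squalene synthase Fdft1 at 1.06 ± 0.24. Of 57 oxidative phosphorylation genes 56 were positive, median 0.52 (adjusted p = 3.26e-13; adjusted p = 0.918 with an estimated correlation), and 11 were higher adjusted over the list alone, with Cox6a1 at 0.79 ± 0.19 and Ndufb7 at 0.70 ± 0.18. The mitochondrially encoded genes went the other way, 12 of 13 negative with a median of -1.09 (adjusted p = 0.0188; adjusted p = 0.918 with an estimated correlation; 0 adjusted over the list alone), with mt-Nd2 at -1.46 ± 0.52 and mt-Nd4l at -1.64 ± 0.60. Ribosomal protein genes were positive in 71 of 74, median 0.66 (adjusted p = 2.49e-11; adjusted p = 0.918 with an estimated correlation; 0 adjusted over the list alone), with Rps15 at 0.95 ± 0.39 and Rpl28 at 0.94 ± 0.40. Tight junction and mucus genes were positive in 23 of 28, median 0.48 (adjusted p = 1.01e-05; adjusted p = 0.65 with an estimated correlation; 0 adjusted over the list alone), with the junction protein Tjp3 at 0.73 ± 0.19 and E-cadherin, Cdh1, at 0.79 ± 0.22.

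Heat shock genes stood lower in tea of set X, 12 of 14 with a median of -1.14 (adjusted p = 0.00288; adjusted p = 0.65 with an estimated correlation). Adjusted over the list alone 4 were lower, among them the Hsp90 partner Chordc1 at -1.48 ± 0.19 and the co-chaperone Dnaja1 at -1.28 ± 0.24. Fibroblast genes were negative in 11 of 12, median -0.98 (adjusted p = 0.00316; adjusted p = 0.918 with an estimated correlation; 0 adjusted over the list alone), with decorin, Dcn, at -1.39 ± 0.44 and Col1a2 at -1.15 ± 0.36. Mesothelium, adipocyte, smooth muscle and interstitial cell genes had medians of -2.42, -2.7, -1.04 and -0.98 (adjusted p of 0.0711 to 0.762). Glutamatergic synapse genes had a median of -0.59 and missed the threshold (adjusted p = 0.0592), with the AMPA receptor subunit Gria3 at -2.07 ± 0.56. General neuron, enteric neuron, glia and synaptic vesicle genes had medians of -0.79, -0.69, -0.74 and -0.55 (adjusted p of 0.186 to 0.514). Saline held 2 of its 3 libraries among the 6 with high muscle and low mucin transcripts and tea held 1; Myh11 stood at 4335 ± 3289 CPM in saline and 1913 ± 1051 CPM in tea, and Epcam at 1426 ± 224 and 1979 ± 206 CPM.

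Within the kind of library that held neither lung nor cartilage transcripts, 2 tea and 2 saline libraries of set X could be set side by side without a test. Both saline libraries, NCX_134 and NCX_147, and 1 of the tea libraries, JHHCGX_256, were among the 6 apart on the first principal component, with mitochondrial shares of 18.87, 17.4 and 12.22% against 6.52% in JHHCGX_148, so this contrast is close to that between libraries apart and not apart. There 22 of 22 cholesterol genes, 54 of 57 oxidative phosphorylation genes and 74 of 74 ribosomal protein genes were higher in tea, with medians of 0.79, 0.6 and 0.93, and 0 of 13 mitochondrially encoded genes were, with a median of -1.59. Of heat shock genes 3 of 14 were higher, median -1.3, of fibroblast genes 1 of 12, median -0.98, and of glutamatergic genes 13 of 55, median -0.8. Nerve cell markers stood alike, with 0 of 15 general neuron genes (median -1.04), 0 of 14 enteric neuron genes (-1.04), 2 of 24 synaptic vesicle genes (-0.84) and 3 of 10 glia genes (-1.01) higher in tea. In these 4 libraries goblet cell genes also differed, 12 of 12 with a median of 3.63, and smooth muscle genes, 1 of 13 with a median of -1.26.

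No single gene passed in the tea comparison of set X with edgeR (0 of 20889), while 3582 had an unadjusted p under 0.05. Limma on FPKM called 0 and DESeq2 1943. Of the genes with the smallest p, all at an adjusted p of 0.0664, the potassium channel Kcnk5 stood at 1.23 ± 0.15, Midn at 1.03 ± 0.14, C77080 at 1.14 ± 0.16, Zfp687 at 1.03 ± 0.15 and Ptprf at 0.99 ± 0.14. On the negative side were Chordc1, Lrif1 at -1.43 ± 0.17, Mphosph8 at -1.56 ± 0.21, Zfp280d at -1.39 ± 0.19 and Zfp638 at -1.51 ± 0.21. Without NCX_124 the count was 540. Across genes, which are not independent replicates, the fold changes had a Spearman correlation of 0.32 with transcript GC content and -0.25 with transcript length.

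The capsule comparison of set X showed cholesterol, oxidative phosphorylation and cell cycle genes above saline and heat shock, smooth muscle and nerve genes below. All 22 cholesterol genes were positive, median 0.53 (adjusted p = 9.05e-08; adjusted p = 0.65 with an estimated correlation), with Mvd at 1.12 ± 0.33. Oxidative phosphorylation genes were positive in 55 of 57, median 0.44 (adjusted p = 1.06e-13; adjusted p = 0.65 with an estimated correlation), with Atp5g1 at 1.86 ± 0.46 and Cyc1 at 0.83 ± 0.24. All 13 mitochondrially encoded genes were negative, median -0.65 (adjusted p = 0.0365; adjusted p = 0.736 with an estimated correlation; 0 adjusted over the list alone), with mt-Nd2 at -0.86 ± 0.51 and mt-Nd4 at -0.85 ± 0.54. Cell cycle genes were positive in 31 of 32, median 0.92 (adjusted p = 7.19e-06; adjusted p = 0.65 with an estimated correlation), with the mitotic kinase Aurka at 1.15 ± 0.66 and Cenpe at 0.85 ± 0.52. Smooth muscle genes were negative in 12 of 13, median -1.43 (adjusted p = 0.000186; adjusted p = 0.65 with an estimated correlation), with the muscle coactivator Myocd at -1.80 ± 0.63 and Actg2 at -1.56 ± 0.58. All 15 neuron genes were negative, median -1.28 (adjusted p = 0.00052; adjusted p = 0.65 with an estimated correlation), with Elavl4 at -1.99 ± 0.87 and Celf4 at -1.47 ± 0.67. Glutamatergic synapse genes, the theme chosen by the study, were negative in 40 of 54, median -0.58 (adjusted p = 0.00435; adjusted p = 0.65 with an estimated correlation), with the glutamine transporter Slc38a1 at -0.79 ± 0.20 and the calcium channel Itpr1 at -1.35 ± 0.40. In each of these lists 0 genes passed adjusted over the list alone. The fold changes of this comparison had a Spearman correlation of 0.14 with GC content and -0.22 with transcript length across genes.

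Heat shock genes were negative in 13 of 14 in the capsule libraries of set X, median -0.74 (adjusted p = 2.82e-05; adjusted p = 0.393 with an estimated correlation), with Dnaja1 at -0.85 ± 0.24 and Chordc1 at -0.62 ± 0.19. Genes of drug and steroid metabolism were positive in 31 of 34, median 0.42 (adjusted p = 7e-05; adjusted p = 0.393 with an estimated correlation), and 3 were higher adjusted over the list alone, with the exporter Abcc3 at 1.71 ± 0.32 and the bilirubin transferase Ugt1a1 at 0.96 ± 0.23. Goblet cell genes were called higher (adjusted p = 0.0286; adjusted p = 0.699 with an estimated correlation) on a mean of 1.57, while their median was -0.36. Capsule held none of the 6 libraries with high muscle and low mucin transcripts and saline held 2. Without those 6 libraries Myocd, Elavl4 and Celf4 stood at 0.32, 0.49 and 0.67, folds that rest on the single saline library NCX_124, which held cartilage transcripts. Between the single capsule and saline library with cartilage transcripts, 18 of 22 cholesterol genes were higher in capsule (median 0.24), 49 of 57 oxidative phosphorylation genes (0.15), 12 of 13 mitochondrially encoded genes (0.13), 1 of 14 heat shock genes (-0.53), 2 of 13 smooth muscle genes (-0.63), 0 of 15 neuron genes (-0.34) and 23 of 55 glutamatergic genes (-0.09).

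No single gene passed in the capsule comparison of set X with edgeR (0 of 20889; 2014 with an unadjusted p under 0.05; limma on FPKM 0, DESeq2 205). The smallest p on the positive side belonged to Osbpl7 (1.27 ± 0.17), Tmem253 (1.56 ± 0.22), Ppargc1b, a coactivator of mitochondrial genes (1.29 ± 0.19), Arhgef19 (1.45 ± 0.22) and the antibody segment Ighv1-39 (7.52 ± 1.23). On the negative side were Arrdc3 (-0.80 ± 0.14), Pcdhga9 (-3.77 ± 0.75), Tppp3 (-1.14 ± 0.23), Pdlim4 (-1.20 ± 0.25) and Mettl16 (-0.91 ± 0.19). Adjusted p ran from 0.496 to 0.517.

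**Figure D2:**
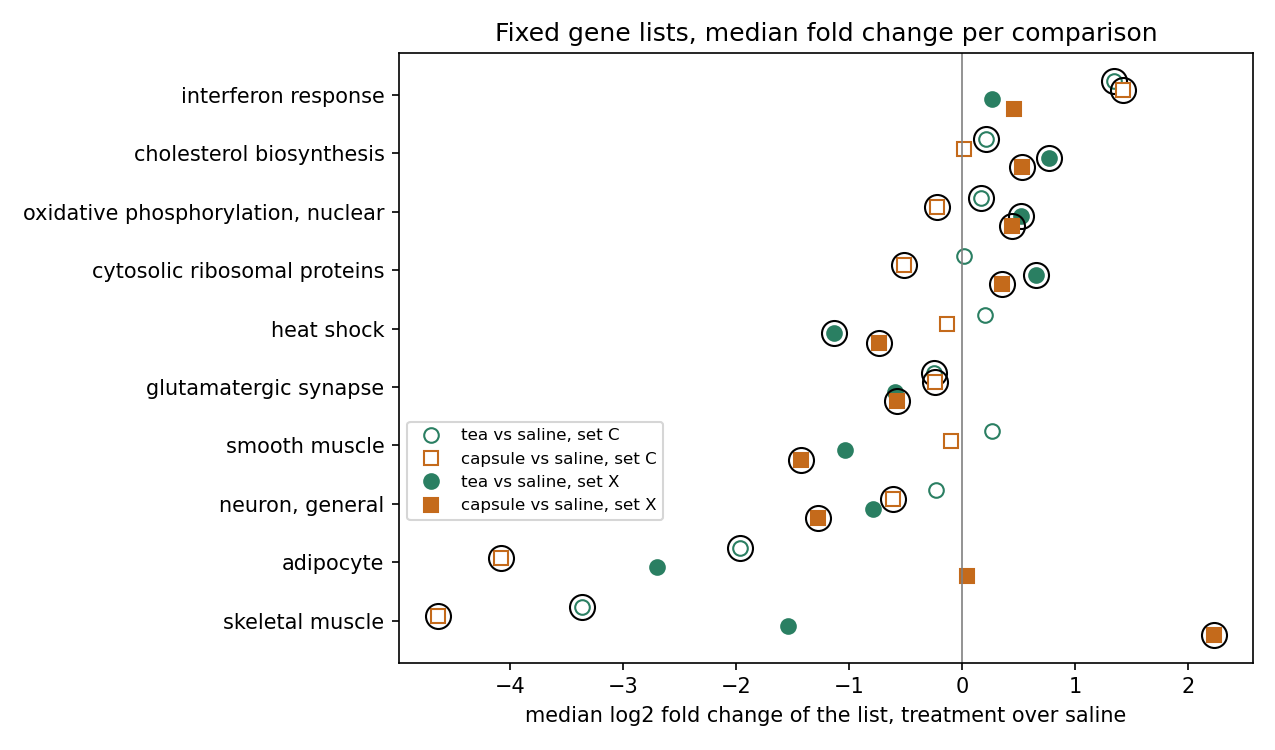
Median log2 fold change (horizontal axis, treatment over saline) of the tested members of 10 gene lists in 4 comparisons; circles are tea, squares capsule, open symbols set C, filled symbols set X, and a black ring marks a camera adjusted p under 0.05. Skeletal muscle genes stood at -3.37 for tea and -4.64 for capsule in set C, but at 2.23 for capsule in set X. Cholesterol genes stood at 0.77 for tea and 0.53 for capsule in set X.

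Tea and capsule were also compared directly in set X. Skeletal muscle genes stood lower in tea, 12 of 12 with a median of -3.96 (adjusted p = 1.22e-13; adjusted p = 0.628 with an estimated correlation; 10 lower adjusted over the list alone), with skeletal actin, Acta1, at -2.54 ± 0.59 and Tnni2 at -3.73 ± 0.94. Cell cycle genes stood lower, 29 of 32 with a median of -0.52 (adjusted p = 0.0129; adjusted p = 1 with an estimated correlation), with Cenpe at -1.39 ± 0.52 and the proliferation marker Mki67 at -1.54 ± 0.62. Cholesterol genes stood higher, 17 of 22 with a median of 0.19 (adjusted p = 0.0129; adjusted p = 1 with an estimated correlation), with Insig1 at 0.72 ± 0.27. Both had 0 genes adjusted over the list alone. The fold changes had a Spearman correlation of 0.33 with GC content across genes. By edgeR 0 of 20889 genes passed (1235 with an unadjusted p under 0.05; limma on FPKM 0, DESeq2 242). The chromatin remodeller Srcap came nearest at 3.89 ± 0.40, with 52.8 ± 5.7 CPM in tea and 3.56 ± 1.37 CPM in capsule (adjusted p = 0.12). Tppp3 (1.02 ± 0.23), Tmem43 (0.96 ± 0.23), Tor2a (0.67 ± 0.16), Slc35e4 (0.82 ± 0.21), Lrif1 (-1.02 ± 0.17), Zfp930 (-1.68 ± 0.29), Zfp944 (-1.22 ± 0.21), Eea1 (-1.05 ± 0.18) and the skin keratin Krt1 (-8.05 ± 1.40) had adjusted p of 0.516 to 0.538. The capsule library FFZRX_139 held Col2a1 at 68.4 CPM and Lep at 51.5 CPM, and both were at 0 in the tea libraries of set X. The fat marker Adipoq stood at up to 54.6 CPM in capsule and up to 5.07 CPM in tea of this set.

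Averaged over both sets, tea differed from saline in 113 genes, 9 higher and 104 lower. The rises were small: Chmp6, a subunit of the membrane-sorting complex ESCRT-III (ENSMUSG00000025371, chromosome 11, 119913441 to 119919548), rose by 0.76 ± 0.15 (adjusted p = 0.04), from 33.8 and 29.6 CPM in saline of sets C and X to 50.5 and 57.0 CPM in tea. Tor2a, a torsin ATPase (ENSMUSG00000009563, chromosome 2, 32757234 to 32762244), rose from 36.6 and 35.7 to 45.2 and 66.9 CPM (adjusted p = 0.0331). The small GTPase Rhog rose by 0.54 ± 0.09 (adjusted p = 0.0331). Pym1, Zfp687, Tbrg1, Tor1a and Suds3 rose by 0.64 ± 0.13, 0.59 ± 0.12, 0.55 ± 0.11, 0.46 ± 0.09 and 0.44 ± 0.09 (adjusted p of 0.043 to 0.0485). Of the genes that fell, Nr1d2, a repressor of the circadian clock (chromosome 14, 18204054 to 18239127), stood at -1.35 ± 0.24 (adjusted p = 0.0331), with 90.3 ± 34.1 and 89.2 ± 9.81 CPM in saline of sets C and X and 40.6 ± 12.4 and 30.7 ± 9.55 CPM in tea. Zeb2, a repressor of epithelial genes, stood at -1.17 ± 0.16 (adjusted p = 0.0316).

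The largest falls of the averaged tea effect included genes that marked the 5 libraries with cartilage transcripts. H19 stood at -4.94 ± 1.01, Col11a2 at -2.69 ± 0.50, the muscle gene Trdn at -3.71 ± 0.76 and Zim1 at -2.88 ± 0.60; 4 of those 5 libraries were saline and none was tea. Dnm3os stood at -1.80 ± 0.37, and the Y-linked helicase Ddx3y at -1.94 ± 0.28 (adjusted p = 0.0316), with 3.77 ± 0.17 and 52.5 ± 7.9 CPM in saline of sets C and X and 0.718 ± 0.38 and 18.8 ± 3.5 CPM in tea. Lrrc2 and Cntnap4 had 0.354 and 0.22 CPM in saline of set C, 0.311 and 0.239 CPM in saline of set X, and 0 in all 6 tea libraries. Fam83a stood at 1.09 and 0.46 CPM in saline and 0.014 and 0 in tea.

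Some gene groups of the tea comparison of set X stood apart in the averaged tea effect, which holds the same libraries and so is no second showing. In set C alone the tea medians were 0.16 for oxidative phosphorylation, 0.21 for cholesterol and -0.49 for fibroblast genes. Oxidative phosphorylation genes were positive in 55 of 57, median 0.33 (adjusted p = 2.74e-15; adjusted p = 0.812 with an estimated correlation), and 12 were higher adjusted over the list alone, with Atp5o at 0.50 ± 0.14 and Atp5d at 0.50 ± 0.14, while all 13 mitochondrially encoded genes were negative with a median of -0.69 (adjusted p = 0.0692). Cholesterol genes were positive in 21 of 22, median 0.50 (adjusted p = 3.35e-09; adjusted p = 0.812 with an estimated correlation), and 10 were higher adjusted over the list alone, with Pmvk at 0.53 ± 0.15. Fibroblast genes were negative in 12 of 12, median -0.77 (adjusted p = 0.000101; adjusted p = 0.812 with an estimated correlation), and 7 were lower adjusted over the list alone, with Col1a2 at -0.90 ± 0.23 and Dpt at -0.98 ± 0.28. Other markers of the gut wall and fat had medians of -1.56 for mesothelium, -2.41 for adipocytes, -0.37 for smooth muscle and -0.73 for interstitial cells of Cajal. Smooth muscle stood at 0.26 in set C and -1.04 in set X. Of the 6 libraries apart on the first principal component 3 were saline and 2 tea. Glutamatergic synapse genes were negative in 46 of 55, median -0.39 (adjusted p = 0.00601; adjusted p = 0.812 with an estimated correlation), and 1 was lower adjusted over the list alone. Among the members of the list, Shank3 stood at -0.70 ± 0.22; the theme is the study's own. General neuron, enteric neuron, synaptic vesicle and glia genes had medians of -0.555, -0.478, -0.378 and -0.593 (adjusted p of 0.0978 to 0.347). Heat shock genes, lower in set X, had a median of 0.21 in set C and missed the threshold in the averaged effect (median -0.4; adjusted p = 0.0599). Ribosomal protein genes, higher in set X, had a median of 0.01 in set C. The clock list missed the threshold (adjusted p = 0.0599, median -0.48; adjusted p = 0.812 with an estimated correlation), while 9 of its 24 genes were lower adjusted over the list alone and 1 over all genes; Dbp stood at -2.26 ± 0.60.

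The 113 genes differed in base composition from the other genes. Fold changes of the averaged tea effect had a Spearman correlation of 0.28 with transcript GC content and -0.21 with transcript length across genes. The 104 lower genes had a median GC content of 40.6% against 56% for the 9 higher and 49.4% for all genes. With each library's GC trend removed, 0 genes passed. The 104 lower genes, chosen for their falls in these same libraries, all stayed negative, with a median of -0.51 against -0.86 before. With the length trend removed 11 passed. With a term for library kind 0 passed, the lower genes keeping a median of -0.87 while their median standard error grew from 0.16 to 0.24. The count was 1587 with the first principal component as a covariate. It was 0 without any 1 saline library of set C, NCX_147, JHHCGC_7, JHHCGC_19, JHHCGX_129 or JHHCGX_148. It was 4, 5, 9 and 5 without FFZRC_5, FFZRC_12, NCX_134 and JHHCGX_256, 57 and 49 without FFZRX_139 and FFZRX_238, and 190, 243 and 414 without FFZRC_24, JHHCGC_48 and NCX_124.

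**Figure D3:**
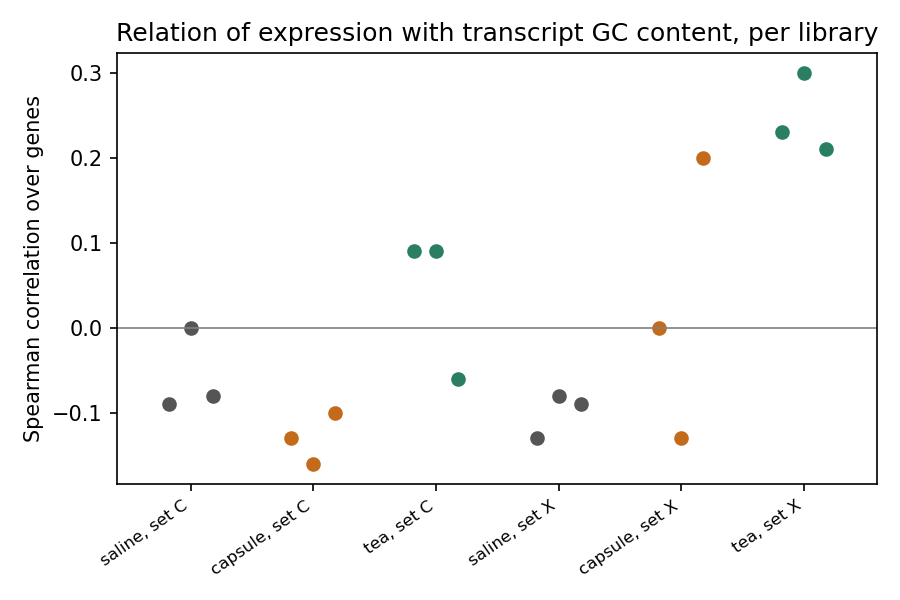
Spearman correlation over genes (vertical axis, no unit) between transcript GC content and a library's log2 CPM less the mean of all libraries, for the 6 groups; dots are libraries. The 3 tea libraries of set X stood at 0.21 to 0.3, above all 15 other libraries, the highest of which was FFZRX_268 at 0.2.

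Averaged over both sets, capsule differed from saline in 1 gene, the Y-linked demethylase Uty (ENSMUSG00000068457, chromosome Y, 1096861 to 1245739), which fell by 1.77 ± 0.23 (adjusted p = 0.0334). Its levels were 1.42 and 25.1 CPM in saline of sets C and X and 0.171 and 17.9 CPM in capsule. The averaged fold thus rests in part on traces of a Y-linked gene in set C, whose libraries all held Xist at 294 to 462 CPM. Ddx3y (-1.86 ± 0.29), Kdm5d (-1.93 ± 0.30) and Eif2s3y (-1.85 ± 0.29), all Y-linked, had an adjusted p of 0.0671. Nerve genes stood lower: 15 of 15 neuron genes with a median of -0.99 (adjusted p = 2.05e-06; adjusted p = 0.54 with an estimated correlation; 1 lower adjusted over the list alone), with Rbfox3 at -1.54 ± 0.39 and Map2 at -1.02 ± 0.38, and 22 of 24 synaptic vesicle genes with a median of -0.94 (adjusted p = 2.65e-06; adjusted p = 0.54 with an estimated correlation; 0 adjusted over the list alone), with Syp at -0.96 ± 0.41. Glutamatergic synapse genes were negative in 44 of 55, median -0.56 (adjusted p = 5.77e-05; adjusted p = 0.54 with an estimated correlation; 0 adjusted over the list alone), with the AMPA receptor subunit Gria2 at -1.66 ± 0.56 and the cyclase Adcy1 at -1.39 ± 0.49, again on the study's theme. Saline held 3 of the 6 libraries with high muscle and low mucin transcripts and capsule held 1.

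Heat shock genes were negative in 14 of 14 in the averaged capsule effect, median -0.37 (adjusted p = 0.000275; adjusted p = 0.54 with an estimated correlation), with Hspa1b at -0.98 ± 0.36 and its near-identical neighbour Hspa1a at -0.96 ± 0.37. Cholesterol genes were positive in 22 of 22, median 0.28 (adjusted p = 5.67e-05; adjusted p = 0.54 with an estimated correlation), with Nsdhl at 0.34 ± 0.14 and Dhcr7 at 0.30 ± 0.14. Interferon response genes were positive in 38 of 39, median 0.96 (adjusted p = 0.000384; adjusted p = 0.685 with an estimated correlation), with Ifi44l at 5.36 ± 1.69 and Psmb9 at 0.81 ± 0.37. Of these 3 lists 0 genes passed adjusted over the list alone. T cell, B cell and plasma cell genes had medians of 1.105, 0.725 and 0.716 in this effect. Not past the threshold were Ppargc1b (0.85 ± 0.14), Tmem253 (0.90 ± 0.18), Mfsd9 (0.86 ± 0.18), Micall2 (0.997 ± 0.21), Kif21b (0.94 ± 0.20) and Sbsn (-1.32 ± 0.23), with adjusted p of 0.0687 to 0.385, and Crispld1 (adjusted p = 0.0671), at 0 in capsule of set C. The single call of Uty was lost with a term for library kind, where it stood at -1.71, and without any 1 of 12 libraries.

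The difference of an effect between the sets was tested directly. For capsule 3 genes differed: Krt10, a keratin of the outer skin layers, by 6.07 ± 0.87 (adjusted p = 0.045), Kdm5d by 4.12 ± 0.61 (adjusted p = 0.045) and Sbsn by 3.85 ± 0.46 (adjusted p = 0.0106). Krt10 went from 21.9 ± 2.08 to 2.43 ± 0.25 CPM in set C and from 2.88 ± 1.25 to 21.5 ± 12.6 CPM in set X. The Y-linked Kdm5d went from 2.10 ± 0.50 to 0.135 ± 0.066 CPM in set C, where all libraries held Xist at 294 to 462 CPM. In set X it went from 33.9 ± 7.6 to 37.3 ± 7.1 CPM. Acta1 (6.72 ± 1.09), Inmt (4.53 ± 0.77), Uty (2.57 ± 0.46), Cyp27a1 (-1.25 ± 0.30), Pds5b (-1.11 ± 0.28), Zfp280d (-0.92 ± 0.24), Camsap2 (-1.35 ± 0.35) and Elp2 (-0.88 ± 0.25) had adjusted p of 0.103 to 0.48. Crispld1 and the skin gene Hrnr, both at 0 in capsule of set C, had adjusted p of 0.136. For tea 0 of 22380 genes differed between the sets by edgeR (1346 with an unadjusted p under 0.05; limma on FPKM 0, DESeq2 118). Ppargc1b (1.502 ± 0.28), the GABA transaminase Abat (1.67 ± 0.34), Kcnk5 (1.31 ± 0.28), Fam83h (1.48 ± 0.32), Mphosph8 (-1.61 ± 0.24), Dek (-1.27 ± 0.23), Tra2a (-1.49 ± 0.27), Zfp280d (-1.25 ± 0.24) and Lrif1 (-1.48 ± 0.29) had adjusted p of 0.199 to 0.414, as did Hes7, at 0.152 CPM or less in every group. The capsule count became 0 with a term for library kind, where Krt10, Kdm5d and Sbsn stood at 5.08, 3.93 and 3.32. That term rested on libraries of set X, because kind coincided with treatment in set C.

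Set X and set C differed in 9 genes, 6 of them on the Y chromosome and 2 on the X. The Y-linked Kdm5d, Eif2s3y, Uty and Ddx3y stood higher in set X by 5.81 ± 0.28, 5.47 ± 0.28, 5.12 ± 0.21 and 4.91 ± 0.26, with adjusted p of 5.4e-09 to 4.96e-08. Xist, the noncoding RNA that silences an X chromosome (chromosome X, 103460366 to 103483254), fell from 294 to 462 CPM in the libraries of set C to 0.909 to 10.2 CPM in set X (adjusted p = 3.7e-07). Kdm6a, an X-linked demethylase, stood at -0.94 ± 0.12 (adjusted p = 0.0036) and Cirbp, a cold-inducible RNA-binding protein on chromosome 10, at 0.84 ± 0.12 (adjusted p = 0.00846). The Y-linked sequences Gm29650 and Gm4017 completed the list. The summed level of the 4 Y-linked genes was 10.38 to 12.3 CPM in the saline libraries of set C and 0.75 to 4.87 CPM in the other 6 libraries of that set. In set X it was 179.26 to 191.57 CPM in saline, 120.5 to 184.7 CPM in capsule and 76.6 to 94.58 CPM in tea.

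**Figure D4:**
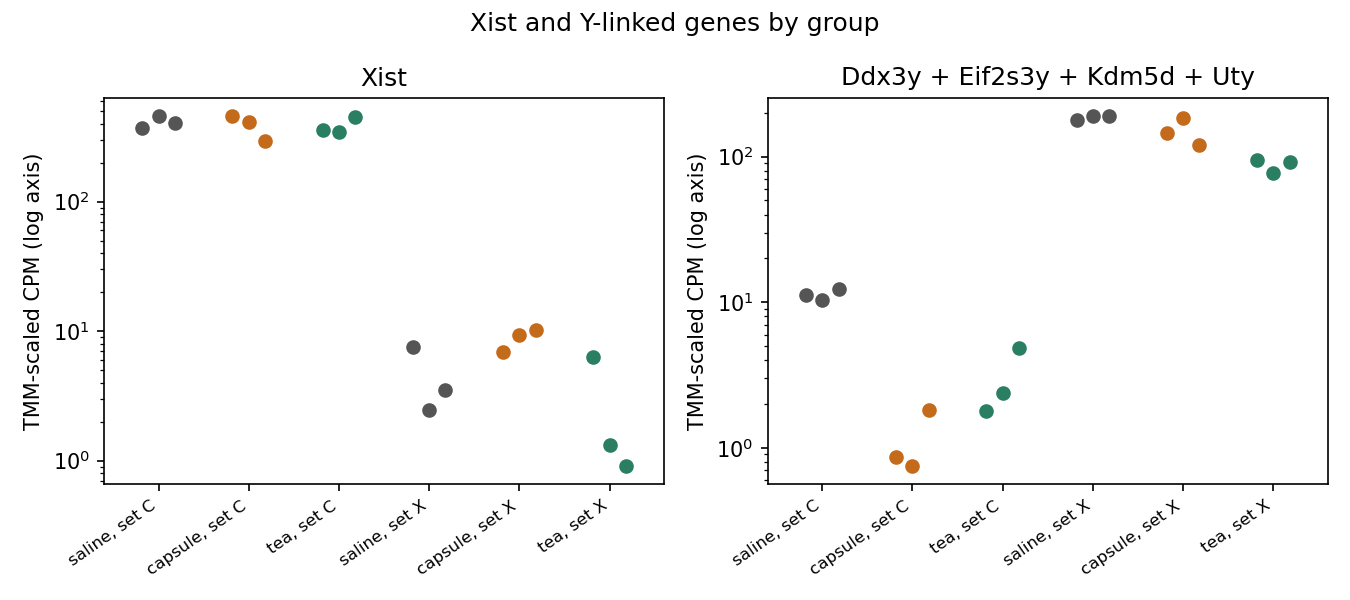
TMM-scaled CPM (log axis) of Xist and of the sum of Ddx3y, Eif2s3y, Kdm5d and Uty in each library of the 6 groups; dots are libraries. Xist stood at 294 to 462 CPM in set C and 0.909 to 10.2 CPM in set X, and within set C the Y-linked sum was 10.38 to 12.3 CPM in saline and 0.75 to 4.87 CPM in the others.

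Tea and capsule were each compared with the same saline libraries, which by itself makes their fold changes alike. Across genes, which are not independent replicates, the tea and capsule folds had a Pearson correlation of 0.64 in set C and 0.624 in set X. Simulated unchanged groups against shared controls gave 0.5 in both sets. Genes were simulated independently, without differences shared by many genes of a library. The excess of the real values over the simulated ones therefore cannot be read as likeness of the treatments. The covariance was 0.459 against 0.273 simulated in set C and 0.463 against 0.274 in set X, differences of 0.186 and 0.189. With the saline libraries split between the comparisons, the mean correlation over 6 splits was 0.289 in set C and 0.103 in set X. The means of each pair of mirrored splits ran from 0.242 to 0.322 in set C and from -0.172 to 0.268 in set X. The single splits may spread further.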

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

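The comparison of effects between the sets was planned before the data were examined, and the comparisons with other splits of the libraries were chosen only after the results were seen.

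The test of the difference in capsule effect between set X and set C singled out 3 genes. Krt10 stood at -3.15 in set C (adjusted p = 0.195) and 2.90 in set X (adjusted p = 0.517), a difference of 6.07. Sbsn stood at -3.22 (adjusted p = 0.0138) and 0.61 (adjusted p = 0.599), a difference of 3.85. Kdm5d stood at -3.94 (adjusted p = 0.132) and 0.14 (adjusted p = 0.874), a difference of 4.12. This Y-linked gene was at trace levels in set C, 2.10 CPM in saline and 0.135 CPM in capsule, against 33.9 and 37.3 CPM in set X. In edgeR with a term for library kind 0 genes differed, with Krt10, Kdm5d and Sbsn at 5.08, 3.93 and 3.32 and adjusted p of 0.883. In set C kind and treatment cannot be told apart, so the term rested on set X and the kept folds do not exclude kind. The epidermis list summed to 21.6 to 181 CPM in libraries with cartilage transcripts. It summed to 7.4 to 77.6 CPM in those with lung transcripts alone and to 5.6 to 13.1 CPM in those with neither. Groups of 3 libraries were too small for a test of single outlying libraries.

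Other splits of the same libraries into groups of the same sizes were run for every count. Within a set there were 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 0 and 0 genes for tea and saline of set C, 23 and 0 for capsule and saline of set C, and 3 and 0 for tea and capsule of set C. In set X they were 0 and 1371 for tea and saline, 0 and 1 for capsule and saline, and 0 and 1 for tea and capsule. For lists they were 20 and 22, 17 and 20, and 13 and 26 in set C, and 13 and 27, 24 and 30, and 5 and 18 in set X, in the same order. The split with 1371 genes set NCX_124, JHHCGX_129 and JHHCGX_148 against NCX_134, NCX_147 and JHHCGX_256. The latter are the 3 of these libraries with high muscle and low mucin transcripts, which points to a structure of the samples other than treatment.

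With both sets, 100 splits were drawn. For the averaged tea effect 3 of 100 splits gave at least the 113 genes, a share under 0.05. The highest other split, with NCC_8 in place of JHHCGC_48, gave 551 genes. For set X against set C 2 of 100 gave at least 9 genes (highest other 560), and for the difference in capsule effect 4 of 100 gave at least 3 genes (highest other 2525). These 3 shares were not adjusted for the number of counts examined, so by themselves they do not exclude chance. Nor was chance excluded for the averaged capsule effect, where 8 of 100 splits gave at least 1 gene (highest other 1047). For the difference in tea effect the real count was 0, which all 100 splits reach whatever the data (highest other 551), so they say nothing about chance there. For lists, 93 of 100 splits gave at least the 10 called for tea (highest other 29) and 12 of 100 at least the 24 called for capsule (highest other 31), so chance was not excluded for either. Counts several times the real ones point to a structure of the samples.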

How the results depend on the processing

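The alternatives with library kind, the first principal component, the 6 libraries apart on it, mitochondrial genes, GC content and transcript length were chosen after seeing the data; the others were planned. Of the alternative values of single genes, 4956 kept direction and side of the threshold, 683 lost it, 404 gained it and 21 reversed. Counts are given below where they moved by more than 1.5 times, and the cause was not tested unless stated. No paired analysis was possible because no replicate number is shared between groups. Shared-control values with single libraries left out were not run. Depth was at least 59206980 counts, and a group with no count of a gene was taken to lie under a floor of 3 counts per library.

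Limma on log2(FPKM + 1) called 50 genes for tea and 105 for capsule against saline in set C, 19 and 0 for the averaged tea and capsule effects and 19 for the capsule difference between sets. A pseudocount of 0.1 gave 16, 64, 10, 2 and 20 in this order, and no variance trend gave 46, 92, 20, 0 and 18. In the capsule difference between sets, Uty reversed to -0.16 with limma, with and without the trend. Library weights called 179, 4912 and 1061 genes in set C (tea and capsule against saline, tea against capsule), 6740, 2389 and 11 in set X, 5489 and 5132 for the averaged effects, 1526 and 882 for the differences between sets and 5226 for set X against set C; Kdm5d in the averaged capsule effect reversed to 0.04 and Uty in the capsule difference to -0.11. DESeq2, in the same order, called 159, 406, 189, 1943, 205, 242, 1402, 149, 118, 143 and 141.

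Library totals without TMM gave 1 gene for tea in set C, 21 and 5 for the averaged tea and capsule effects and 5 for the capsule difference. For the averaged tea effect median-ratio scaling gave 62, no filter on low counts 1, and removal of the GC trend 0. The length trend removed gave 1 for tea against capsule in each set and 11 for the averaged tea effect. A mean FPKM of 5 or more, with fewer genes tested, gave 5 for capsule in set C, 159 for tea in set X, 202 and 0 for the averaged effects, 0 for the capsule difference, 5 for set X against set C, and 10, 9 and 0 lists for tea in set C, capsule in set C and tea against capsule in set X. Other libraries in the fit gave 6 for capsule and 0 for tea against capsule in set C, 448 for tea in set X, 4 and 2 for the averaged effects and 7 for the capsule difference.

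A term for library kind gave 0 genes for capsule against saline and tea against capsule in set C, both averaged effects and the capsule difference, and 22, 14 and 25 lists for tea in set X, tea against capsule in set X and the averaged tea effect. In tea against saline of set C it reversed Oc90 to 3.10, Matn1 to 2.09, Lipe to 0.12 and Lep to 1.05. In capsule against saline of set C it reversed Scgb1a1 to 0.78, Sftpd to 0.13, Cyp2b10 to 0.81, Lep to 5.14, Rps28 to 0.28 and Ager to 0.18. In tea against capsule of set C it reversed Scgb1a1 to -0.03, Rps29 to -0.17 and Rps28 to -0.26. The first principal component as a covariate gave 16 and 78 genes for tea and capsule in set C, 549 for tea in set X, 1587 and 14 for the averaged effects, 8 for the capsule difference, 16 for set X against set C, and 9 and 18 lists for tea against capsule in set X and the averaged tea effect. Without the 6 libraries apart on it, capsule in set C had 215 genes and tea against capsule in set C 11. In set X this left NCX_124, with cartilage transcripts, as the only saline library. Against it, Myocd in capsule of set X reversed to 0.32, Elavl4 to 0.49 and Celf4 to 0.67.

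An estimated correlation left 0 lists in all 8 comparisons. Fry called 2 and 6 lists for tea and capsule in set C and 0 in the other 6 comparisons. The shared-control correlation was 0.626 in set C and 0.558 in set X with a prior count of 0.1, and 0.289 and 0.103 with the saline libraries split.

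Leaving out single libraries gave 0 to 11 genes for tea and 2 to 240 for capsule in set C and 1 to 9 for tea against capsule. In set X it gave 0 to 540 for tea, 0 to 0 for capsule and 0 to 1 for tea against capsule, the 540 and 1 without NCX_124. For the averaged effects it gave 0 to 414 and 0 to 12, for the tea difference 0 to 1 (1 without JHHCGC_19), for the capsule difference 0 to 10 and for set X against set C 8 to 12. The averaged capsule count was 0 without NCC_2, NCC_8, NCC_17, NCX_124, NCX_134 or NCX_147, FFZRC_5, FFZRC_12, FFZRX_238 or FFZRX_268 or JHHCGX_148 or JHHCGX_256, 3 without JHHCGC_7, JHHCGC_19 or FFZRX_139, 6 without JHHCGC_48 and 12 without FFZRC_24. The capsule difference was 0 without NCC_2, NCC_17, NCX_134 or NCX_147 or FFZRC_5, 1 without NCC_8, FFZRC_12, FFZRX_139, FFZRX_238 or FFZRX_268 or JHHCGX_129, JHHCGX_148 or JHHCGX_256, 7 without FFZRC_24, 8 without JHHCGC_19 and 10 without NCX_124. Lists ran from 13 to 22 for tea in set C (13 without NCC_17), 15 to 21 for capsule and 12 to 21 for tea against capsule (21 without FFZRC_24). In set X they ran from 13 to 26 for tea (22 without NCX_124, 26 without JHHCGX_256), 20 to 29 for capsule and 4 to 13 for tea against capsule (8 without NCX_134, 12 without FFZRX_268 or JHHCGX_129, 13 without JHHCGX_148, 9 without JHHCGX_256). They were 11 to 25 for the averaged tea effect (17 to 19 without NCC_2, NCC_8 or NCC_17, JHHCGC_7, JHHCGC_48 or JHHCGX_129 or FFZRX_268, 25 without NCX_124 or JHHCGX_256) and 23 to 30 for capsule.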

Other observations

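In this part the tests of GC content and transcript length were fixed before their results were seen; the other tests were chosen only after the results were seen.

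In the averaged tea effect 16 of 24 clock genes were negative and 8 positive. Dbp (-2.26 ± 0.60), Per3 (-1.21 ± 0.33), Per2 (-0.83 ± 0.27), Tef (-1.02 ± 0.35) and Ciart (-1.68 ± 0.59) stood below saline, and so did the activators Clock (-0.45 ± 0.14) and Rora (-1.12 ± 0.30). The activators Arntl and Npas2 stood at 0.72 ± 0.40 and 0.73 ± 0.36 and the repressors Cry1 and Nfil3 at 0.36 ± 0.58 and 0.28 ± 0.46, none past the test over the list alone (adjusted p of 0.106 to 0.575). In set X alone Npas2 stood at 0.84 ± 0.27 and passed over the list alone (adjusted p = 0.0488). With the GC trend removed, Dbp, Per3 and Per2 stood at -2.31, -1.25 and -0.92, Clock at -0.10, Rora at -0.77, Arntl and Npas2 at 0.79 and 0.69, and Nr1d2 at -1.03 (adjusted p = 0.176). Over the list alone 9 genes were lower, and of single genes only Nr1d2 passed over all genes. Against saline, capsule had medians of 0.17 in set C (adjusted p = 0.195) and -0.08 in set X (adjusted p = 0.228). Tea against capsule had a median of -0.36 in set C (adjusted p = 0.000169; adjusted p = 0.654 with an estimated correlation) and -0.22 in set X (adjusted p = 0.813), so a difference between the treatments was not shown in set X. In 2 tea and 2 saline libraries of set X with neither lung nor cartilage transcripts, 5 of 24 clock genes were higher in tea; both saline libraries and 1 of the 2 tea libraries are among the 6 apart on the first principal component. The hour of tissue collection is not given in the labels.

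T cell genes stood higher than other genes after both treatments averaged over the sets, 14 of 15 with a median of 1.13 for tea (camera adjusted p = 0.0171; adjusted p = 0.812 with an estimated correlation) and 14 of 15 with 1.11 for capsule (adjusted p = 0.00519; adjusted p = 0.584 with an estimated correlation), and 0 passed adjusted over the list alone. Between the single capsule and saline library of set X with cartilage transcripts, T cell genes went the other way, 3 of 15 positive with a median of -0.94. In the same 2 tea and 2 saline libraries of set X, 11 of 15 were positive with a median of 0.64. Tuft cell genes stood higher after capsule in set X, 6 of 9 with a median of 0.99 (adjusted p = 0.00594; adjusted p = 0.65 with an estimated correlation), and 3 were higher adjusted over the list alone. The KEGG term for the glutamatergic synapse in the deposited annotation stood lower in the averaged capsule effect, median -0.21 over 106 genes (adjusted p = 0.0137; adjusted p = 0.671 with an estimated correlation), and in capsule of set C, median -0.14 (adjusted p = 0.0498; adjusted p = 0.692 with an estimated correlation). In the averaged capsule effect the terms for the GABAergic synapse (median -0.341, adjusted p = 0.00822) and circadian entrainment (median -0.392, adjusted p = 0.00752) stood lower by more, both with an adjusted p of 0.671 with an estimated correlation. The glutamatergic term missed the threshold after tea, with medians of -0.15 in set C (adjusted p = 0.0877), -0.36 in set X (adjusted p = 0.497) and -0.26 averaged (adjusted p = 0.188).

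The 6 libraries apart on the first principal component held 53.5 to 925.5 CPM of Fabp2, a fatty acid binder of enterocytes, against 17.4 to 334.9 CPM in the other 12. Hoxb13, a homeobox gene of the hindgut end, stood at 47.1 to 264 CPM against 114.5 to 437.2 CPM. No test separated position along the gut, the layers of its wall and RNA quality as sources of this difference.

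The 23 genes lower in capsule than in saline of set C had a median log2 fold change of -4.97 with genes at 0 set to their bound. Lowering by the capsule in both sets was examined through set X. Those of these genes that were tested there had a median of 0.14, and 11 were positive. The capsule libraries FFZRX_139, FFZRX_238 and FFZRX_268 all held lung transcripts, while the saline libraries NCX_134 and NCX_147 held neither kind. This layout may by itself raise such genes in capsule, so the median cannot decide on lowering by the capsule. Tissue taken along when the same mice were dissected was examined through Y-linked transcripts. The lowest saline library of set C held 2.13 times the Y-linked sum of the highest other library of that set. Xist was as high in saline (410 CPM) as in capsule and tea (389 and 385 CPM). These values cannot decide on dissection, because no test showed that the Y-linked reads came with the reads of other tissues. Of the 22 genes other than Sftpc, 21 were higher in both set X libraries with cartilage transcripts than in the 4 of set X with neither kind, an order seen in 17.2% of all tested genes. A candidate explanation is therefore reads of other tissues, from a source that the 5 libraries may share. How they entered, at dissection or otherwise, is open, and in set C an effect of the capsule on top of them is untested.

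The 104 genes lower after tea, averaged over both sets, had a median of -0.86 with a median standard error of 0.16. With the GC trend of each library removed the median was -0.51 (standard error 0.15) and with the length trend removed -0.65 (standard error 0.16), so that part of the difference may follow base composition or length; calls ended because the folds shrank. With a term for library kind the median was -0.87, the median standard error was 0.24 and 0 genes passed. The standard error is derived from the same test, so its growth does not explain why the calls ended. The kept median argues against kind as the whole cause only if kind acts alike in both sets. In set C kind and treatment cannot be told apart, so the term rested on libraries of set X. All 104 genes stayed negative under these 3 settings, but they had been chosen for their falls in the same libraries, so this outcome was close to fixed in advance. What remains after the GC trend is removed leaves a response to tea open as a hypothesis that no further test addressed.

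The 9 genes that part set X from set C were mostly X- and Y-linked. Reads carried between libraries as the whole cause were argued against by Xist, which was 29 times higher in the lowest library of set C than in the highest of set X. Of 5 X-linked genes known to escape inactivation, 5 were lower in set X: Kdm6a at -0.94 ± 0.12, Eif2s3x at -0.80 ± 0.15, Pbdc1 at -0.65 ± 0.20, Kdm5c at -0.64 ± 0.15 and Ddx3x at -0.37 ± 0.14, of which Kdm6a alone passed over all genes. This is consistent with mice of another sex in each set, female in set C and male in set X, which the labels do not state. The Y-linked sum in saline of set C, 7.96% of the mean of set X, may come with the reads of other tissues, which would then have a male source.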
